A study of Mus musculus with 121 samples.

How the data were processed

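Single cells from the bone marrow of C57BL/6 mice carrying the R412X allele of Gfi1 were profiled by RNA sequencing. The labels write the genotype as Gfi1-R412X/- in one place and as HTZ in another, and both forms apply to all 121 cells. Per the labels' protocols, marrow was taken from crushed hindlimbs, enriched on CD117 (Kit) beads, stained and sorted by flow cytometry. Cells were then captured and lysed on the Fluidigm C1 microfluidic system, cDNA was made with the SMARTer kit and libraries with Nextera XT. The labels sort the cells into 2 populations, 46 cells called CD11b+ GMP-P and 75 cells called GMP. CD11b is the integrin alpha M chain, encoded by Itgam and carried by maturing myeloid cells. Cells with an unmutated Gfi1 were not analysed here, so no comparison below measures the effect of the mutation.

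Bowtie2, RSEM and the mm9 build are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. By its deposited values, the authors' table holds log2 expression of 23946 genes in 121 cells. Back-transformed as 2 to the power of the value minus 1, each cell summed to between 999517 and 1001450, which is what TPM values give, with TPM rounded to 2 decimals. Of all values, 81.7% were 0. TPM keeps no record of the number of reads, so the sequencing depth of each cell is unknown, and a 0 can mean a transcript that was missed. A second deposited table of the authors gives the other kind of value used here, a state name for each cell, with 12 different names. How those states were assigned is not given in the sources used here. State names are used as deposited and their abbreviations are not expanded. Gene symbols were used as deposited: 22653 of the 23946 are current mouse symbols in GENCODE vM21, and 23829 are current symbols, RefSeq names or synonyms. That reference is on another genome build than mm9, so no coordinates are given.

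Labels carry a run name. All 46 CD11b+ GMP-P cells carry 1 run name, dated late July, and the GMP cells carry 3 others. Of these, 2 also give a late July date, for 10 cells without a year and for 3 cells with one, and they were pooled as 13 late July GMP cells. The other 62 GMP cells share a run name without a date and are called other GMP or the other run. No run name is shared by the populations, so population and run name are fully tied, and only the date joins the 13 cells to CD11b+ GMP-P. Values against late July GMP are given for each list and for part of the genes. No label names an animal, so each population counts as 1 sample. No p-value, standard error or count of changed genes was computed from cells. Means are given ± SD over cells, which describes the spread of single cells and is no replicate error. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. A share of 0 carries instead the upper limit set by 3 cells, which is lower than the exact limit: 6.52% against 7.71% for 0 of 46 cells. Intervals and limits cover counting error only.

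A gene was called detected in a cell at a TPM of 1 or more. Differences between populations are differences of mean log2(TPM + 1), CD11b+ GMP-P minus GMP, and this scale understates differences of low genes. The 9150 genes detected in at least 10% of the cells of either population were kept. For each gene list fixed before the data were examined, the median difference over kept members is given. Its percentile among 10000 random lists of the same size, matched on mean level in 50 bins, is a description of these libraries and no test. The lists cover primary granule, secondary and tertiary granule, neutrophil effector and receptor genes, granulocyte transcription factors, monocyte and dendritic transcription factors, and monocyte markers. They also cover genes described as repressed by Gfi1, stem and multilineage genes, S phase, G2 and M phase, ribosomal proteins, interferon response, immediate early and heat shock genes, and genes used in sorting. A further set of 11 marker lists covers other cell types. Lists overlap: Irf8, Zeb2, Id2 and Egr1, for example, stand in both the Gfi1-repressed and the monocyte and dendritic factor lists.

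Genes are named by a rule fixed before the data were examined. It takes Gfi1, Irf8 and the sort genes, and up to 4 members of each list with the largest absolute difference. It also takes the 10 largest differences in each direction among genes detected in at least 50% of the cells of the higher population and of the same sign against late July and other GMP. For each state it takes up to 5 markers with the largest difference from all other cells. Elane, Serpinb1a, Hdc, Slc40a1, Ear2, Cd79b and Retnlg fall outside that rule and were named after their values were seen. Not every gene the rule takes is reported. Genes used in the sort are a check of the sort. The states are names the authors gave to these same cells, so genes that separate states are given as a description of the annotation and are no independent result.

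On simulated data for CD11b+ GMP-P minus GMP, with 200 of 9150 genes changed by a log2 of 3, the median recovered difference was 2.92 without dropout. It was 0.998 when each gene's values were set to 0 at its rate over all 121 cells, the same in both populations. All 20 changed lists lay above the percentile of 97.5 in both cases, and 4 and 6 of 100 unchanged lists lay outside 2.5 to 97.5. Differences of rarely detected genes are thus compressed. The simulation held no difference in detection between the populations, so it does not show how the percentiles behave under one. The highest correlation between any pair of cells, across genes, was 0.728, so no 2 cells held the same values. Doublets were not called, and all 121 cells were kept. A comparison within states was set for states with at least 8 cells of each population, and no state had them. Alternatives were other pseudocounts, filters, averages, scaling between cells, detection thresholds, restriction to either run of GMP, removal of cells with outlying gene number, and Leiden clusters in place of the annotation. Clusters used the most variable genes, 10 principal components, 10 neighbours and a resolution of 1, and were named after a marker list that held at least 3 of the 5 markers highest in them. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9, and figures matplotlib 3.10.9.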

Results

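The series asks how a Gfi1 mutation linked to neutropenia bears on the cell states passed through during granulocyte specification and commitment. The part used here holds single bone marrow cells of Gfi1-R412X mice, 46 labelled CD11b+ GMP-P and 75 labelled GMP. Each population is 1 sample without replicates, because no animal is named. CD11b+ GMP-P cells had a median of 2870 detected genes (range 967 to 4738) and GMP cells 4354 (1436 to 6153). Within GMP the 13 late July cells had a median of 2570 and the 62 other cells 4521. The 20 most abundant genes took a median of 32.9% of the TPM in CD11b+ GMP-P cells, 52% in late July GMP cells and 11.5% in other GMP cells. S100a8, S100a9 and Ngp led them, with mean levels of 85741, 71663 and 50181 TPM in CD11b+ GMP-P. Over all 9150 genes kept, the median difference of CD11b+ GMP-P minus GMP was −0.56. It was 0.18 against late July GMP and −0.69 against other GMP, and the values below stand beside those shifts.

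Itgam, which encodes CD11b, was detected in 35 of 46 CD11b+ GMP-P cells (76.1%, 61.2 to 87.4) and in 16 of 75 GMP cells (21.3%, 12.7 to 32.3). This checks the sort and is no finding. Within GMP, however, Itgam was detected in 11 of 13 late July cells (84.6%, 54.6 to 98.1) and in 5 of 62 other cells (8.06%, 2.67 to 17.8). Cd34, a surface marker of early progenitors, differed by −4.41 between the populations and was detected in 28.3% of CD11b+ GMP-P, 38.5% of late July GMP and 98.4% of other GMP cells. Kit, the receptor used for bead enrichment, differed by −1.91. Fcgr3 and Ly6c2, also surface markers of myeloid progenitors, differed by −0.34 and 0.23. Ly6a, Ly6c1 and Fcgr2b differed by 0.29, 0.16 and −0.86 and Ly6g, a marker of mature neutrophils, by 0.88, with −0.18, 1.03, 0.74 and −1.08 against late July GMP. Flt3 was detected in 0 of 46 CD11b+ GMP-P cells, which allows a share of up to 6.52%, and in 1 of 75 GMP cells. The sort genes as a list had a median difference of −0.09, both pooled and against late July GMP.

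Gfi1, the mutated gene and a repressor of transcription needed for neutrophil formation, was detected at similar rates in both populations. It was detected in 32 of 46 CD11b+ GMP-P cells (69.6%, 54.2 to 82.3) and in 57 of 75 GMP cells (76%, 64.7 to 85.1). Mean log2(TPM + 1) was 4.50 ± 3.73 in CD11b+ GMP-P and 4.95 ± 3.61 in GMP (SD over cells), a difference of −0.45. Against late July GMP the difference was −0.61 and against other GMP −0.41. The sign turned under scaling of the cells to one upper quartile (0.07) and for the ratio of mean TPM (0.04). By state, mean Gfi1 was highest in Gran-1 (7.36) and Gran-2 (7.34) and lower in Mono (4.11), Myelo-2 (4.57) and Myelo-4 (1.78). Gene-level values do not tell the mutant transcript from another allele.

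**Figure D1:**
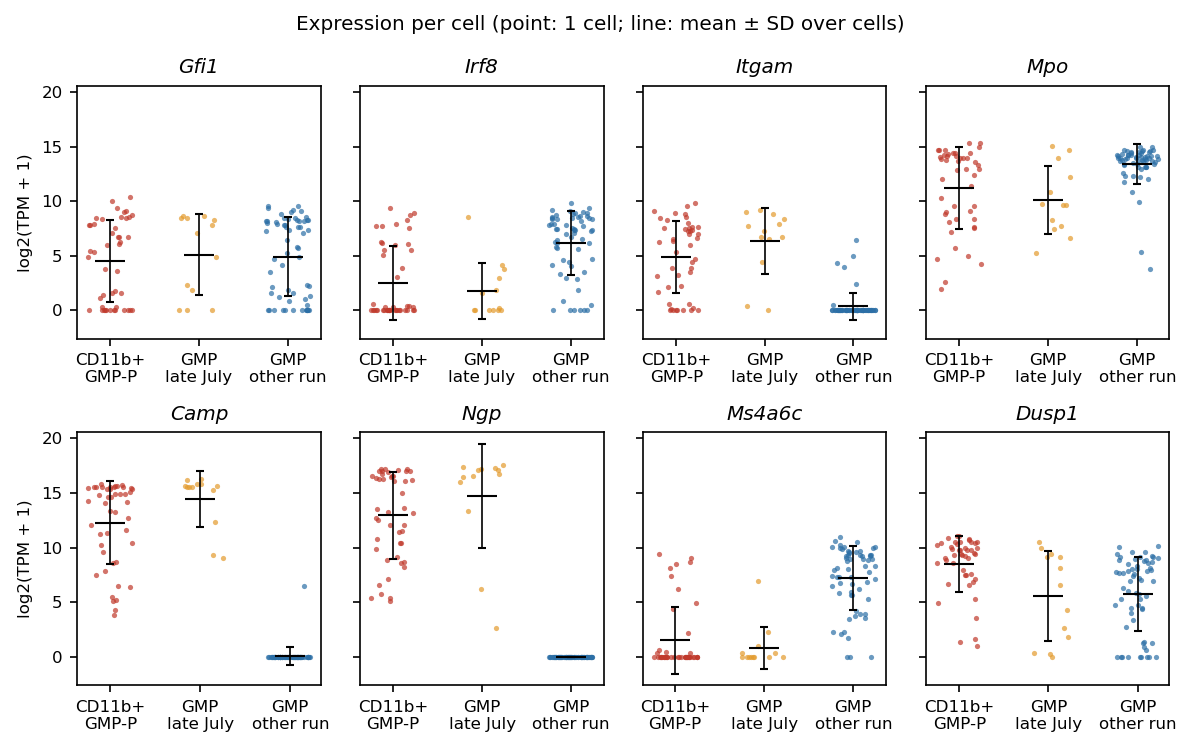
Expression of 8 genes per cell, as log2(TPM + 1) on the y axis, in CD11b+ GMP-P (46 cells), late July GMP (13 cells) and other GMP (62 cells); each point is 1 cell and the lines give the mean ± SD over cells. Gfi1 overlaps among the 3 sets, with means of 4.50, 5.12 and 4.92, while Ngp is listed at 0 in all 62 other GMP cells and is above 0 in all late July cells of both populations.

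The first comparison asked which states each sorted population held. CD11b+ GMP-P was mostly granulocytic: 40 of 46 cells (87%, 73.7 to 95.1) carried a Gran or Myelo state, against 23 of 75 GMP cells (30.7%, 20.5 to 42.4). Mono was the largest state of GMP, with 32 of 75 cells (42.7%, 31.3 to 54.6), and held 6 of 46 CD11b+ GMP-P cells (13%, 4.94 to 26.3). The split followed the run as well as the population. All 13 late July GMP cells (100%, 75.3 to 100) carried Gran or Myelo states, against 10 of 62 other GMP cells (16.1%, 8.02 to 27.7). Myelo states held 24 of 46 CD11b+ GMP-P cells, 10 of 13 late July GMP cells and 0 of 62 other GMP cells, which allows a share of up to 4.84%. Mono held 0 of 13 late July GMP cells, which allows up to 23.1%, and 32 of 62 other GMP cells (51.6%, 38.6 to 64.5). Gran-1 and Gran-2 held 3 and 13 CD11b+ GMP-P cells and 11 and 2 GMP cells. The 11 MP, 5 cMoP, 2 Multi-Lin, 1 MDP and 1 HSCP-1 cells were all from the other run of GMP, and each of these states held 0 of 46 CD11b+ GMP-P cells, which allows a share of up to 6.52%.

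**Figure D2:**
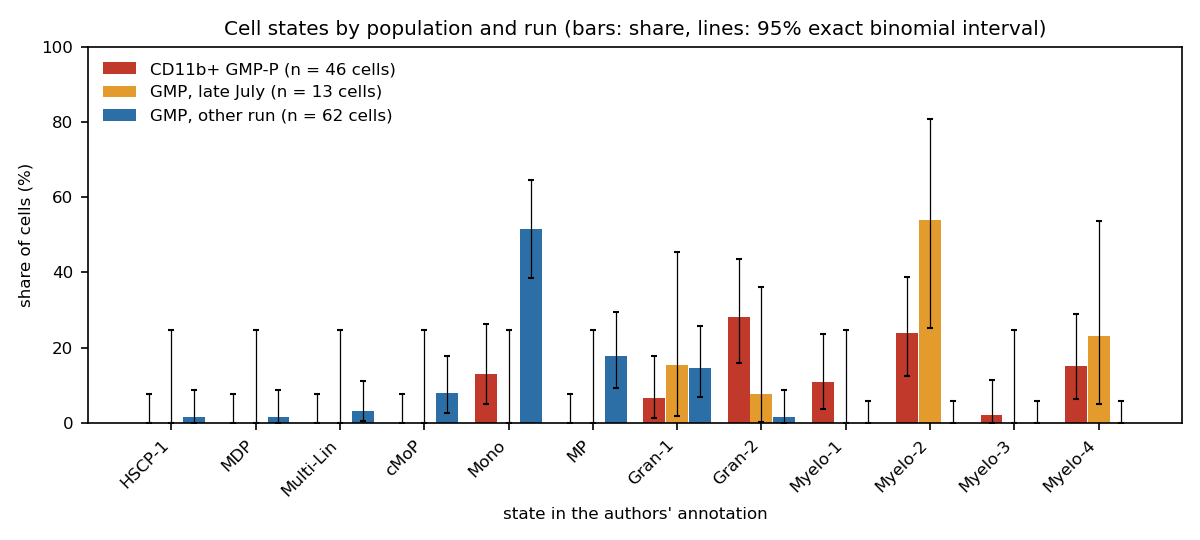
Share of cells in each of the 12 states of the authors' annotation (x axis), in percent (y axis), for CD11b+ GMP-P (46 cells), late July GMP (13 cells) and other GMP (62 cells); bars are shares and lines exact 95% binomial intervals. Mono holds 51.6% of other GMP cells and 0% of late July GMP cells, and Myelo-2 holds 53.8% of late July GMP cells.

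Described by their markers, the states ran from monocytic genes to granule genes. Irf8, a transcription factor of monocyte and dendritic cell formation, averaged 7.63 in Mono, 8.66 in cMoP and 0.47 in Myelo-4. Ms4a6c, Ctss (cathepsin S) and F13a1 (a coagulation factor subunit made by monocytes) averaged 8.27, 6.96 and 6.17 in Mono. Ly86, F13a1 and Ccr2, the receptor of monocyte chemokines, were markers of cMoP at 8.57, 8.55 and 8.16. MP was led by Cd34 (7.96) and Ctsg (11.67), the gene of cathepsin G. Gran-1 was led by Vcam1 (4.65), Gfi1 and Ctsg (11.83), and Gran-2 by Chil3 (12.80), Fcnb (9.75) and Camp (10.50). Ngp, Ltf (lactoferrin) and Camp (cathelicidin), proteins of neutrophil secondary granules, averaged 16.52, 13.13 and 15.45 in Myelo-2 and 17.06, 14.27 and 15.51 in Myelo-4. Mpo, the myeloperoxidase of primary granules, averaged 14.19 in Gran-1, 13.71 in Mono and 6.23 in Myelo-4. Myelo-1, with 5 cells, was led by Camp (13.19) and Ngp (13.33), and the single Myelo-3 cell by Ngp (16.50).

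**Figure D3:**
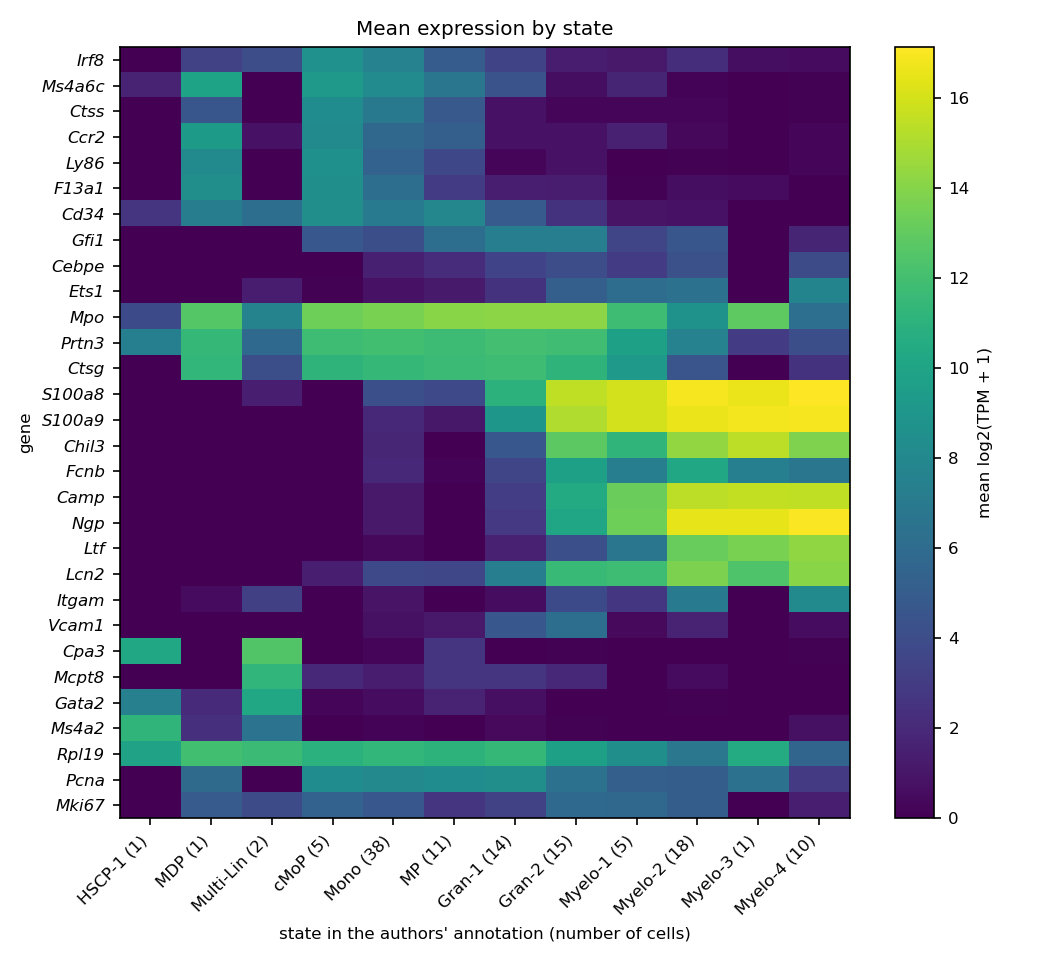
Mean log2(TPM + 1), as colour, of 30 genes (rows) in the 12 states of the authors' annotation (columns, number of cells in brackets). Irf8 averages 7.63 in Mono and 0.47 in Myelo-4, and Ngp runs from 0 in MP to 17.06 in Myelo-4.

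Genes of secondary and tertiary granules and of neutrophil function were higher in CD11b+ GMP-P than in GMP, and this did not hold within the late July date. All 15 measured secondary and tertiary granule genes were higher, with a median difference of 4.34 (percentile 100). Ngp differed by 10.39, Camp by 9.69, Chil3, a chitinase-like protein, by 9.35 and Lcn2, an iron-sequestering protein, by 6.76. As log2 ratios of mean TPM these were smaller, at 1.5, 1.58, 2.08 and 1.81. Of 17 effector and receptor genes 15 were higher, with a median of 1.79 (percentile 100). S100a9 and S100a8, the subunits of calprotectin, differed by 10.40 and 9.30, Trem1 by 3.75 and Itgb2, the partner chain of CD11b, by 2.99. Within the late July date 0 of 15 granule genes were higher and the median turned to −1.27 (percentile 0), with Camp at −2.18, Ngp at −1.79 and Ltf at −3.58. The effector list turned to −0.63 (percentile 0). Against other GMP the medians were 5.46 and 2.31.

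Primary granule genes, expressed earlier in neutrophil development, were mostly lower in CD11b+ GMP-P. Of 8 members 7 were lower, with a median of −1.53, which was ordinary for genes of that level (percentile 48.2). Ctsg differed by −2.77, Prtn3 (proteinase 3) by −2.22, Ctsc by −1.68 (0.02 for the ratio of mean TPM) and Mpo by −1.61. Elane, neutrophil elastase, differed by −1.46, and Serpinb1a, its inhibitor, was the member that was higher (1.05), and both turned against late July GMP (1.32 and −0.84). The list turned to 0.77 against late July GMP (percentile 98.7), with 7 of 8 members higher and Mpo at 1.12.

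Among granulocyte transcription factors 3 of 10 were higher and 7 lower, with a median of −0.67 (percentile 81.1). Ets1 differed by 3.45 and Cebpe, a factor of secondary granule genes, by 1.48, while Myb, a factor of proliferating progenitors, differed by −1.88 and Etv6 by −1.69. Of 9 monocyte and dendritic factors 4 were higher and 5 lower, with a median of −0.68 (percentile 47.7) that turned to 0.72 for the ratio of mean TPM. Irf8 differed by −2.86, Zeb2 by −1.84 and Tcf4 by −1.17, and Id2, an inhibitor of helix-loop-helix factors, by 2.11. Of these, Irf8, Zeb2, Tcf4, Myb, Etv6 and Ets1 had the opposite sign against late July GMP (0.75, 0.38, 0.44, 0.59, 0.55 and −0.15), and Cebpe and Id2 were at 0.17 and 0.42, near the shift of all genes. The granulocyte list was then at 0.57 and the monocyte and dendritic list at 0.42.

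Monocyte markers were lower in CD11b+ GMP-P: 12 of 16 members, with a median of −1.35 (percentile 5.91). Ms4a6c differed by −4.56, Ctss by −3.56, Ccr2 by −3.18 and Cst3 (cystatin C) by −3.01. The median was 0.06 against late July GMP (percentile 21.8), and Cst3 stayed at −1.32 while Ms4a6c, Ctss and Ccr2 were at 0.70, 0.31 and 0.97. Genes described as repressed by Gfi1, which share Irf8, Zeb2 and Id2 with the factor list, had a median of −0.63 (percentile 59.5), with 3 of 12 higher and 9 lower. Bax, a promoter of apoptosis, differed by −1.56. That list was at 0.25 against late July GMP (percentile 63).

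Ribosomal protein genes were lower in CD11b+ GMP-P in all 22 members, with a median of −2.23 (percentile 0.32), and not against late July GMP, where the median was 0.04 (percentile 41). Rplp1 differed by −3.27, Rps24 by −2.80, Rps4x by −2.79 and Rpl19 by −2.73. All 20 S phase genes were lower, with a median of −1.19 that was ordinary for their level (percentile 63.1). Mcm7 and Mcm3, subunits of the replicative helicase, differed by −2.35 and −2.12, Cdt1 by −1.97 and Pcna by −1.96. G2 and M phase genes, by contrast, did not follow the general shift: 10 of 20 were higher and the median was −0.00 (percentile 100), or 0.30 after upper quartile scaling. Mki67 differed by 0.84, Nusap1 by 0.57, Cdc20 by −1.21 and Birc5 by −0.69. S phase genes against late July GMP were at 0.30 (percentile 53.4) and the G2 and M list at 0.38 (percentile 57.1). Stem and multilineage genes had a median of −0.59 (percentile 53.7), with 8 of 10 lower, among them Ifitm1 at −3.45, Meis1 at −1.08 and Sox4 at −0.84, and a median of 0.09 against late July GMP. The 5 measured interferon genes had a median of 0.10 (percentile 98), with Irf7 at 0.56, Ifit2 at −0.52 and Bst2 at −1.27, and against late July GMP a median of 0.44 (percentile 92.8). The sign of the pooled interferon value turned without a filter and for the mean over members.

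Immediate early and heat shock genes were higher in CD11b+ GMP-P against late July GMP and against other GMP. Of 13 members 12 were higher, with a median of 1.11 (percentile 100). The median was 1.34 with 13 of 13 higher against late July GMP and 1.20 with 11 of 13 higher against other GMP, both at percentile 100. Dusp1, a phosphatase that turns off MAP kinases, averaged 8.55 ± 2.56 in CD11b+ GMP-P, 5.57 ± 4.11 in late July GMP and 5.76 ± 3.38 in other GMP. Btg2, an antiproliferative gene, averaged 8.55 ± 3.69, 5.32 ± 5.10 and 5.90 ± 3.23, and Zfp36, which speeds the decay of inflammatory transcripts, 8.40 ± 2.73, 5.62 ± 3.74 and 5.92 ± 2.98. Hspa1a, an inducible heat shock protein, differed by 1.52, with 0.27 against late July GMP.

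**Figure D4:**
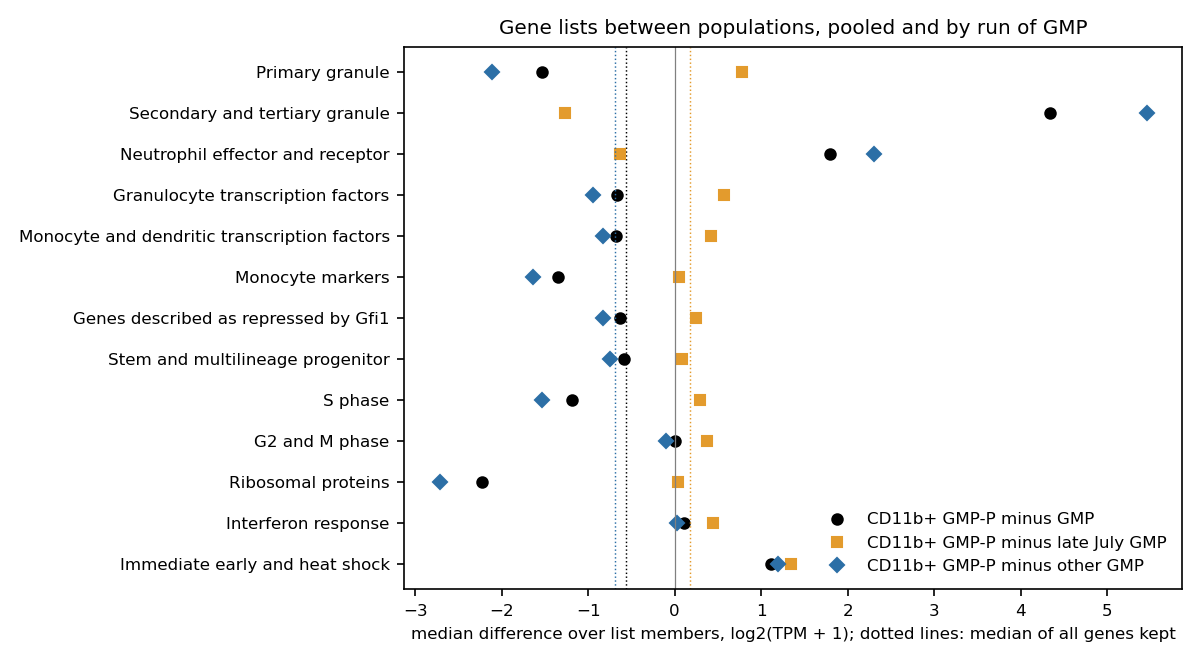
Median difference over the members of 13 gene lists (rows) on log2(TPM + 1) (x axis), for CD11b+ GMP-P minus all GMP (circles), minus late July GMP (squares) and minus other GMP (diamonds); dotted lines give the median over the 9150 genes kept for each. Secondary and tertiary granule genes lie at 4.34 pooled and −1.27 against late July GMP, and immediate early genes lie at 1.11, 1.34 and 1.20.

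Among single genes detected in at least 50% of the higher population and of one sign against late July and other GMP, Clec4a2, a lectin receptor, had the largest positive difference (4.01). Lsp1 (3.79), Trem1 (3.75), Klf6 (3.47), Lrg1 (3.34), Il1f9 (3.21), Actn1 (3.01), Dusp1 (2.82), Pilra (2.78) and Gsn, the actin-severing gelsolin (2.77), followed. Against late July GMP Dusp1 (2.98) and Klf6 (1.27) stayed above 1, and the other 8 lay between 0.12 and 0.57. The largest negative differences were of Cd34 (−4.41), Prdx2, a peroxide-reducing enzyme (−4.38), Naa38 (−4.22), Psmb8, an immunoproteasome subunit (−4.16), Rn4.5s (−4.01) and Snrpf, a splicing protein (−3.96). Dad1 (−3.92), Nme1 (−3.87), Romo1 (−3.84) and Sepw1 (−3.80) came next. Against late July GMP Rn4.5s (−1.76), Naa38 (−1.51), Romo1 (−1.26) and Snrpf (−1.09) kept a difference beyond 1.

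Of the marker lists, Neutrophil progenitor genes had a median of 1.05 (percentile 100; 8 of 15 higher), with secondary granule genes higher and most primary granule genes lower. Gstm1, a member, differed by −2.12, Fcnb by 5.62 and Ltf by 6.11. All 10 Monocyte progenitor markers were lower, with a median of −2.45 (percentile 0), among them F13a1 (−2.31), Ly86 (−2.58) and Cx3cr1 (−0.60). Against late July GMP these lists were at −0.61 and 0.73. Dendritic markers, 4 of them measured, were at −0.68, stem and multilineage markers, also 4, at −0.72, and erythroid markers, 2 measured, at −0.47, with 0.13, −0.25 and −0.46 against late July GMP. Basophil and mast markers, 4 measured, were at −0.51, with Mcpt8 at −1.15 and Hdc, histidine decarboxylase, at 1.04, and the list turned to 0.40 against late July GMP. The macrophage markers Vcam1 and Slc40a1 were at 1.26 and 2.29, and at 0.63 and −0.72 against late July GMP. The lone measured eosinophil marker, Ear2, differed by 1.47 and the lone B lineage marker, Cd79b, by −1.98, with 0.01 and 0.21 against late July GMP. T and NK markers, 2 measured, were at −1.03 with Nkg7 at −1.96 (list at 0.38 against late July GMP), and 0 of 10 megakaryocyte markers passed the filter.

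Within states, both granule lists and the effector list were higher in CD11b+ GMP-P in Mono, and the immediate early list in Mono and in Myelo-2. The difference between the 2 states was not tested. No state held 8 cells of each population, the number set before the data were examined, so states with at least 5 of each were used, a choice made after seeing the data. Mono held 6 CD11b+ GMP-P cells and 32 GMP cells, all from the other run. Myelo-2 held 11 CD11b+ GMP-P cells and 7 GMP cells, all late July. In Mono the immediate early list had a median of 2.45 (percentile 100), with 12 of 13 members higher, Dusp1 at 4.50 and Zfp36 at 3.20. In Myelo-2 it was at 2.10 (percentile 100), with 9 of 13 members higher, Dusp1 at 3.81, Btg2 at 5.62 and Hspa1a at −1.66. The secondary and tertiary granule list was at 2.5 (percentile 100) in Mono and at −0.30 (percentile 51) in Myelo-2, where 11 of 15 of its members were lower. Primary granule genes were at 0.84 (percentile 98.8) in Mono, with 7 of 8 higher. In Myelo-2 they were at −0.34 (percentile 41.3), with 8 of 8 lower. The effector list was at 0.89 (percentile 99.2) in Mono and at −0.16 (percentile 60) in Myelo-2. Ngp was detected in all 6 Mono cells of CD11b+ GMP-P, at 7.45 ± 2.01, and averaged 0.00 in the Mono cells of GMP. Gfi1 differed by 0.45 in Mono and 0.10 in Myelo-2, and ribosomal proteins by −0.51 (percentile 3.22) and −0.63 (percentile 4.96). S phase genes were at 0.52 (percentile 90.2) in Mono and at −1.26 (percentile 0.805) in Myelo-2, with 13 of 20 lower there and Mcm7 at −5.10.

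Gfi1 and Irf8 oppose each other in the choice between granulocyte and monocyte fates, so their detection in the same cell was counted. Both were detected in 14 of 46 CD11b+ GMP-P cells (30.4%, 17.7 to 45.8) and in 45 of 75 GMP cells (60%, 48 to 71.1). Gfi1 without Irf8 was found in 18 of 46 CD11b+ GMP-P cells (39.1%, 25.1 to 54.6) and in 12 of 75 GMP cells (16%, 8.55 to 26.3). Irf8 without Gfi1 was found in 3 of 46 and 15 of 75 cells, and neither in 11 of 46 and 3 of 75. Within GMP, both were detected in 5 of 13 late July cells (38.5%, 13.9 to 68.4) and in 40 of 62 other cells (64.5%, 51.3 to 76.3). By state, both were detected in 28 of 38 Mono cells (73.7%, 56.9 to 86.6), 8 of 14 Gran-1 cells, 4 of 15 Gran-2 cells and 1 of 10 Myelo-4 cells. Gfi1 without Irf8 was found in 0 of 38 Mono cells, which allows up to 7.89%, and in 10 of 15 Gran-2 cells (66.7%, 38.4 to 88.2). Fewer genes were detected in Myelo-4 than in Mono cells (medians of 1686 and 4657), and a missed transcript counts as not detected here.

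Late July and other GMP cells differed from each other in the same granule and effector lists as the 2 populations did, and by more. Late July minus other GMP, the secondary and tertiary granule list was at 7.80 (percentile 100; 15 of 15 higher), the effector list at 3.63 (percentile 100) and the primary granule list at −3.15 (percentile 0.99). Monocyte markers were at −1.65 (percentile 31.3), the Monocyte progenitor markers at −4.19 (percentile 0; 0 of 10 higher) and ribosomal proteins at −2.77 (percentile 2.75). Monocyte and dendritic factors were at −1.67, granulocyte factors at −1.67 and genes described as repressed by Gfi1 at −1.40. Over all kept genes the median was −0.85. Immediate early and heat shock genes were at −0.28, above matched lists (percentile 99.2).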

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

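Restriction to states with at least 5 cells of each population and removal of the 20 most abundant genes were chosen after seeing the data; the other alternatives were set before. Sequencing depth is unknown because TPM keeps no read number, and CD11b+ GMP-P cells had fewer detected genes than GMP cells (medians of 2870 and 4354), which limits what can be said of rarely detected genes. No paired analysis was possible because the numbers in the labels only name cells and each population is 1 sample. Averaging within states with at least 8 cells of each population was not run, since no state held them. Where a value changed below, the cause was not tested unless stated.

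Of 155 alternative values of gene lists 22 changed sign, and of 504 values of 84 named genes 42 did. Counting a sign change only for lists outside the middle 95% of random lists and genes that differed by at least 1, these were 12 and 36; another 28 and 162 moved by over 1.5 times or across those bounds, and 115 and 306 did neither. The other sign changes started from values inside those bounds. Being outside the bounds does not mean far from 0: the pooled G2 and M phase list was at −0.00139 and the interferon list at 0.10. Except with GMP limited to late July, all lists in the stricter count were G2 and M phase or interferon, moving across 0 from those small values. Of 47 shares and Gfi1 levels 12 moved out of the reported interval, or to a Gfi1 difference of at least 1. The immediate early and heat shock list was above 0 under all 12 alternatives, from 0.89 with a pseudocount of 10 to 1.87 with upper quartile scaling.

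Most sign changes came with the run of GMP. With GMP limited to late July the median of all genes changed sign too, from −0.56 to 0.18, and part of the changes below follow that shift. Granulocyte factors (percentiles 81.1 pooled and 78.4 against late July GMP) and genes described as repressed by Gfi1 (59.5 and 63) stayed ordinary for their level. Ribosomal proteins, monocyte markers and stem and multilineage genes stayed below the median of all genes. With GMP limited to late July, 11 of 13 lists changed sign: the secondary and tertiary granule list turned from 4.34 to −1.27, the effector list to −0.63, ribosomal proteins to 0.0362, G2 and M phase to 0.38, primary granule genes to 0.77, granulocyte factors to 0.57, monocyte and dendritic factors to 0.42, monocyte markers to 0.06, genes described as repressed by Gfi1 to 0.25, stem and multilineage genes to 0.09 and S phase to 0.30. Interferon genes moved to 0.44. Among 84 named genes 39 changed sign, among them 35 that differed by at least 1 in the pooled comparison. Sort genes that only the sort put among the named genes are not in this count. Those higher in the pooled comparison were lower: Itgam −1.50, Ngp −1.79, Camp −2.18, Chil3 −1.03, Lcn2 −1.27, S100a9 −1.22, S100a8 −0.97, Itgb2 −1.44, Ets1 −0.15, Fcnb −1.59 and Ltf −3.58. Those lower in the pooled comparison were higher: Irf8 0.75, Ctsg 0.65, Prtn3 0.25, Ctsc 0.90, Mpo 1.12, Myb 0.59, Etv6 0.55, Zeb2 0.38, Tcf4 0.44, Ms4a6c 0.70, Ctss 0.31, Ccr2 0.97, Bax 0.46, Ifitm1 0.52, Meis1 0.0398, Cdt1 0.33, Pcna 0.0824, Rps24 0.29, Bst2 0.58, Ly86 0.85, Mcpt8 0.84, F13a1 1.19, Nkg7 0.50 and Gstm1 0.14, and of smaller pooled differences Sox4 0.13, Cpa3 0.13, Gata2 0.38 and Cx3cr1 0.03. In the 13 late July GMP cells, 38.5% had both Gfi1 and Irf8, 38.5% Gfi1 alone, 100% a Gran or Myelo state and 0% Mono. With GMP limited to the other run, G2 and M phase was at −0.10, interferon at 0.0319 and the share of Gran or Myelo states 16.1%, and 83 of 84 named genes stayed within 1.5 times.

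Averages and scaling moved several lists. As the log2 ratio of mean TPM, where all genes had a median of −0.38, secondary and tertiary granule genes were at 1.63, monocyte and dendritic factors at 0.72, monocyte markers at −1.08, stem and multilineage genes at −1.66, G2 and M phase at 0.23, ribosomal proteins at −1.20 and interferon at 1.23, while Ctsc (0.0180) and Gfi1 (0.04) changed sign and 63 of 84 named genes moved. With upper quartile scaling, where all genes also had a median of −0.38, effector genes were at 2.79, G2 and M phase at 0.30, ribosomal proteins at −1.20, interferon at 0.25 and immediate early genes at 1.87, and Gfi1 changed sign (0.07). With the mean over members, G2 and M phase was at −0.0542 and interferon at −0.14.

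Pseudocounts and filters moved few lists, though a pseudocount of 10 moved 42 of 84 named genes. A pseudocount of 0.1 put G2 and M phase at −0.0699, interferon at 0.0578 and immediate early genes at 1.76, and one of 10 put monocyte markers at −0.76 and G2 and M phase at 0.0519. Without a filter the interferon list was at −0.00303. With genes detected in at least 50% of cells, monocyte markers were at −2.31 and G2 and M phase at 0.0127, and no interferon gene was left, so that list has no value. Without the 7 GMP cells of outlying gene number, G2 and M phase was at −0.12 and interferon at 0.0289.

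Averaged over Mono and Myelo-2, the states with at least 5 cells of each population, secondary and tertiary granule genes were at 1.31, effector genes at 0.60, G2 and M phase at 0.18, ribosomal proteins at −0.67, interferon at 0.16 and immediate early genes at 1.85. The granule and effector averages join opposite signs: 2.5 and 0.89 in Mono, and −0.30 and −0.16 in Myelo-2. Without the 20 most abundant genes, G2 and M phase was at 0.12 and interferon at 0.14. At a detection threshold of 10, Gfi1 was detected in 61.3% of GMP cells and both Gfi1 and Irf8 in 44%, which a stricter threshold lowers by construction. Leiden clusters named after monocyte progenitor markers held 76% of GMP cells, 77.3% at resolution 0.5, 73.3% with more variable genes, 76% with 5 principal components and 76% without the cell cycle lists. The clusters so named also took in cells of the MP, Gran or Myelo states: at resolution 0.5, 11 MP and 10 Gran or Myelo cells among 64.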

Other observations

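The HSCP-1 and Multi-Lin cells, all other GMP, were led by genes of basophils and mast cells. The 1 HSCP-1 cell had Ms4a2 and Fcer1a, chains of the IgE receptor, at 11.22 and 8.59, Cpa3, a mast cell protease, at 10.29, and the transcription factors Gata2 and Gata1 at 7.44 and 6.89. The 2 Multi-Lin cells averaged 12.48 for Cpa3, 11.27 for Mcpt8, a basophil protease, 10.26 for Gata2 and 8.96 for Fcer1a. Vcam1, an adhesion molecule also made by marrow macrophages, was detected in 71.4% of Gran-1 and 80% of Gran-2 cells, with means of 4.65 and 6.19, against 1.71 in Myelo-2 and 0.80 in Mono.

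All tests of the patterns below were chosen only after the result was seen, though upper quartile scaling itself was set before the data were examined. No biological explanation was tested for the late July cells or for Ngp, since the labels name no other group.

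All 13 late July GMP cells carried granulocytic states, Ngp and Camp. Among the other 62 GMP cells, 10 carried a Gran state and none a Myelo state, and Ngp was detected in 0 and Camp in 1. A gain in detection over the whole run, which bringing in Ngp and Camp would take, would raise other genes too. Of the genes in no list, 86.1% were detected in a lower share of these cells than of the other GMP cells. Their lower median of detected genes (2570 against 4521) already implies this, and so do their states, with medians of 2448.5 in Myelo-2 and 4657 in Mono. The share thus argues against a gain alone in cells made up like the other GMP cells, and not against a gain in granulocytic cells. RNA carried over from the CD11b+ GMP-P cells would add granule transcripts without removing others, though as TPM is a share, added RNA lowers the values of the rest. The Monocyte progenitor markers lay at −4.19, against −0.85 over all kept genes, and at percentile 0 among lists matched on level. That percentile largely restates the states of these cells, none of which was Mono. It argues against carry-over alone into cells made up like the other GMP cells, and not against carry-over into granulocytic cells. The monocyte markers, looked at first, lay at 31.3 and excluded nothing. A wrong population label cannot be told apart from granulocytic cells rightly sorted as GMP. Itgam was detected in 84.6% of late July GMP cells and in 76.1% of CD11b+ GMP-P cells, as a wrong label would give. It was detected in 100% of Myelo-2 cells of both populations, but all GMP cells of Myelo-2 were late July cells. No other GMP cell carried a Myelo state, so whether rightly sorted GMP cells of such states have Itgam is unknown. Outside the Myelo states Itgam was detected in 1 of 3 late July GMP cells (33.3%). These are too few to set beside the Mono cells, with 83.3% in CD11b+ GMP-P and 9.38% in GMP. A gate drawn differently on that date was not tested.

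Immediate early genes such as Dusp1, Btg2 and Zfp36 were higher in CD11b+ GMP-P. A different make-up of states would end the difference within states, and the lower percentile of Mono and Myelo-2 was 100. This covers those states only, and not differences in make-up inside a state. In Mono, moreover, all GMP cells were from the other run. The median of the list minus that of all genes was 1.67 as reported and 2.25 after upper quartile scaling. Zeros do not move with scaling, so this value itself depends on the scaling and cannot exclude it. The list alone stayed higher in CD11b+ GMP-P after upper quartile scaling, so that choice of scaling did not remove the difference. Handling of the 2 sorted fractions cannot be told apart from the populations: the percentile with GMP limited to late July was 100 too, but each fraction is a population and the run names differ as well. A response of the cells to sorting or to capture, a difference between runs, or a difference between the populations in the marrow, may each lie behind it.

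Ngp was detected in 46 of 46 CD11b+ GMP-P cells, the 6 Mono cells included, in 13 of 13 late July GMP cells and in 0 of 62 other GMP cells, which allows a share of up to 4.84%. A second cell of a Myelo state in the chamber would bring a large part of its Ngp, and the highest Mono cell had 1.04% of the mean of the Myelo cells, but Gran cells had as little as 40.5 TPM, within the Mono range of 34.9 to 966. Transcripts carried over from other wells would keep their proportions: Ltf per Ngp had a median of 2.46% in the Mono cells against 14.8% over all CD11b+ GMP-P cells, but ranged from 0.136% to 122%, Camp per Ngp was closer (24% against 44.5%), and Retnlg was detected in 0 of 6 where the proportions would give 8.47 TPM. With 6 cells, carried-over transcripts, a second cell of a Gran state and expression by Mono cells cannot be told apart. Nor can a difference between runs in Mono, since Ngp was detected in 100% of late July GMP cells but none of these carried that state. Within Gran-1, Ngp was detected in the 3 CD11b+ GMP-P cells and in the 2 late July GMP cells, at 6.21 and 2.67 in the latter. Ngp and Camp were 0 in all 9 other GMP cells of Gran-1. In that state Ngp thus went with the date in both populations, over few cells. A difference between runs, carried-over transcripts or a different make-up inside the state would each give this. Ngp in Mono cells may come from carried-over transcripts, a second cell, their own expression or a difference between runs.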
